A study of Homo sapiens with 6 samples.

How the data were processed

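Small RNA of SW480-ADH cells, an adherent line derived from a human colon cancer, was measured on 6 arrays. Cells had received 1,25(OH)2D3, the active hormone form of vitamin D, or its vehicle isopropanol for 24, 48 or 96 h. At each time the extracts of treated and vehicle cells were labelled directly with Cy3 and Cy5 and hybridised together on 2 arrays, per the labels' protocols. Both arrays of a time hold the same pair of extracts, so they are technical repeats of 1 biological replicate. The arrays carry spotted probes for miRNAs of several species.

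Arrays were scanned in 2 colours and quantified with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited intensity values used here are mean spot brightness and median local background in each channel, which the authors left as scanned. The deposited value table holds log10 ratios of Cy5 over Cy3 after the dye normalization of that software. Each of its columns lay within rounding, at most 0.005, of the scanner's own log ratio and its column medians were 0. Those log10 values were not turned for the dye swap, so the table does not settle the direction of the comparison.

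The labels disagree about the dyes. The design text and the labelling protocol describe a dye swap, while the dye fields put vitamin D RNA in Cy3 on both arrays of each time. Before the data were examined, replicate 1 was set as its dye fields read and replicate 2 as swapped. If replicate 2 is instead the array whose fields are right, every sign turns. The names of the deposited data mark replicate 2 as the exchanged array, but not which dye held the treated RNA on either. A check against the miRNA of the series title had been planned and was not used, since it would take the answer as given. Which reading holds is thus unsettled, and results are given by side: a positive value lies on the side of the comparison on which miR-22 lies, and a negative value on the other. The side of miR-22 fixes only this convention.

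Intensities were background-corrected in limma 3.58.1 (R 4.3.3) with the normexp method at an offset of 50 and normalised within each array by loess, with control spots at weight 0. Control spots were taken by name, and 181 spots were blank. Spots that the scanner software marks as non-uniform or population outliers were left out of loess and of all averages. This marking hits bright spots most, between 37.1% and 72.8% of human spots with a mean log2 intensity above 10, so averages with these spots kept were added. Leaving them out as the main choice was settled after both versions had been seen. No spot was saturated. Spots of 1 name were averaged, then the 2 arrays of a time were turned to one direction and averaged; a time has a value only where both arrays do.

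A human miRNA was to be tested where most of its spots were well above background in at least 1 channel on both arrays of a time. That mark is set in at least 94.1% of spots in each channel of each array, and all 469 human names passed it, so the planned filter removed none. A stricter filter was therefore added after seeing the data: a mean log intensity above the 95th percentile of the array's blank spots on both arrays of at least 1 time, which 415 miRNAs passed. With outlier spots left out, 440 miRNAs had values at 2 or 3 times and entered the mean test, and 399 had all 3.

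The mean effect over the 3 times was tested in limma (lmFit and eBayes, intercept against 0, two-sided) with Benjamini-Hochberg adjustment, and a trend as the slope on log2 time, which leaves 1 residual degree of freedom per miRNA. At a single time, with 1 pair of extracts, no test was made: a miRNA passed a size rule where both arrays lay on the same side by at least 1.5-fold. Errors at a single time are array-to-array standard errors from a limma fit of the 6 arrays with a term for each time. The replicate number, which is the dye orientation, was a block in that fit. These errors thus leave out a dye effect that is equal at all times, and the 2 arrays of a time can differ by more. Deviations of arrays of the same number from the time means were correlated over miRNAs above the blank spots. The correlation was 0.72 between the 24 and 48 h arrays, 0.79 between 24 and 96 h and 0.86 between 48 and 96 h. This shows a dye effect that recurs at each time. The values would be the same with the 2 numbers of a time exchanged, so they do not test whether the numbers pair arrays across times. P-values from fits to single arrays measure array-to-array spread only, not the spread between cultures.

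The 21 miRNA lists were written before the data were examined. Lists with at least 3 members measured at all 3 times were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry beside it. Named miRNAs are the one in the series title, those past an adjusted p of 0.05 in the mean test, the 10 largest on each side among those on one side on all 6 arrays, the 5 largest on each side past the size rule at each time, and up to 4 members of each list with the largest mean difference. Other miRNAs named below were chosen after their values were seen, and the text says so.

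Each slide holds the 2 arrays of 1 time, so slide and time cannot be told apart. Alternatives covered the dye orientation, the background correction, the normalization, the filter, the deposited log10 table, each array or time left out, the arrays fitted separately with or without the block, the variance model and the size rule. The spread between times in the simulation was raised to the root mean variance after a first run, with similar results. In simulated data 200 of 469 miRNAs were changed, with noise like that of the arrays with outlier spots kept. For the mean test a spread between times at that root mean variance was added, the same for every miRNA. The mean test recovered 95.7% of those changed by 0.585 on the log2 scale. In the data this spread differed between miRNAs, with an SD over times of 0.009 for miR-520a* and 0.66 for miR-146a. The share recovered thus does not carry over to miRNAs with a wide spread. For the trend test no spread between times was added. On the dye-swap averages it recovered 85.3% of those with a slope of 0.2925 per doubling of time. The noise was drawn as normal, no values were missing and a large share was changed, so these shares are taken as optimistic. None of these settings was varied. Of the calls, 2.42% in the mean test and 3.56% in the trend test were false. A simulated list of 10 miRNAs shifted by 0.34 had an unadjusted camera p under 0.05 in 100% of the runs. Its members were drawn as independent. In the data the miR-17-92 list had an estimated correlation between members of 0.36, so that share does not carry over to it.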

Results

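The arrays compared miRNA levels in colon cancer cells given 1,25(OH)2D3 with those in vehicle-treated cells. The series title names miR-22 as raised by vitamin D. SW480-ADH cells attach strongly and carry the vitamin D receptor, and their 3 treatment times were 24, 48 and 96 h. Each time has 1 pair of extracts on 2 arrays, and this number limits the precision of every value below. Each array held 2592 spots, 1092 of them for 469 human miRNAs. Median Cy3 brightness ranged from 105 to 201 over the 6 arrays against median backgrounds of 76 to 100, and median Cy5 brightness ranged from 91.7 to 112 against 79 to 94. Between 273 and 459 human miRNAs per array lay above the 95th percentile of that array's blank spots. The fewest were on replicate 1 at 24 h, where the 95th percentile of the local Cy3 background was 359.

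The first question was whether dyes had been exchanged between the arrays of a time. Within a time the Cy5 over Cy3 log ratios of the 2 arrays correlated over miRNAs at 0.48 at 24 h (n = 364), 0.48 at 48 h (n = 389) and 0.06 at 96 h (n = 388). The planned criterion of a clearly negative correlation was therefore not met. Dye bias is specific to each probe and cancels in changes between times where it is equal at both, so these changes were compared after seeing the data. The change from 24 to 48 h correlated between the 2 orientations at -0.19 (n = 353), that from 24 to 96 h at -0.40 (n = 354) and that from 48 to 96 h at -0.49 (n = 373). These correlations are across miRNAs, which are not independent replicates. Opposite changes are what exchanged dyes give, as the design text states. Which of the 2 arrays is labelled correctly stays unsettled. With replicate 1 read as labelled, miRNAs on the side of miR-22 were lower with vitamin D, opposite to the series title. With replicate 2 read as labelled they were higher, as the title has it.

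**Figure D1:**
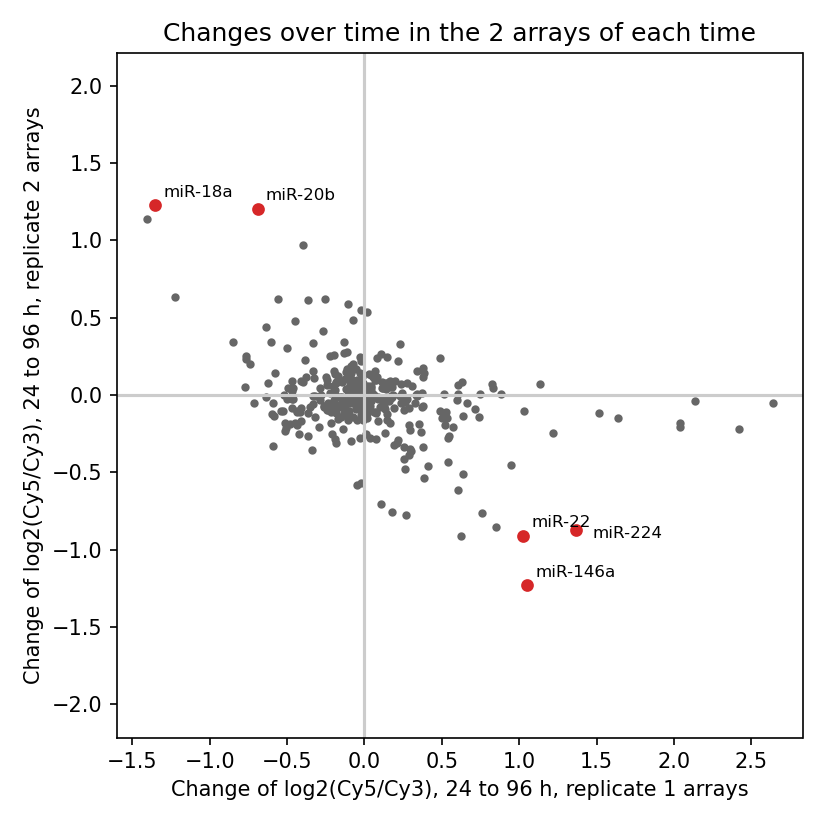
Each point is 1 human miRNA above the blank spots; the x axis gives the change of its log2(Cy5/Cy3) ratio from 24 to 96 h on the replicate 1 arrays and the y axis the same change on the replicate 2 arrays. Over 354 miRNAs the correlation was -0.40, and miR-22, miR-146a, miR-224, miR-18a and miR-20b lay in the quadrants of opposite change.

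Of the human miRNAs measured at 96 h, miR-22 showed the largest difference on its side, and its difference was larger at each later time. Its log2 ratio was 0.36 ± 0.05 (array-to-array SE) at 24 h, 0.78 ± 0.05 at 48 h and 1.32 ± 0.05 at 96 h, or 2.50-fold at 96 h. This error is the spread left after a dye effect, 0.33 for miR-22, is taken as equal at all times and removed. The single arrays differed by more. Replicates 1 and 2 lay at 0.65 and 0.06 at 24 h, 1.13 and 0.44 at 48 h, and 1.68 and 0.97 at 96 h. All 6 arrays thus lay on one side, with replicate 2 near 0 at 24 h. The human miR-22 spot that was never marked as an outlier lay on that side on every array. The other 2 human spots and the rat spot did so too, but they were marked as outliers on 3 or 4 of the 6 arrays and left out there. The mean over the 3 times was 0.82 ± 0.49 (SD, n = 3 times), with an adjusted p = 0.584 in limma.

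At 96 h, 8 miRNAs passed the size rule of 1.5-fold on both arrays, 6 on the side of miR-22 and 2 on the opposite side. On the side of miR-22 were miR-222, with a log2 ratio of 1.26, and miR-221, with 1.13; this pair is transcribed from neighbouring genes and represses the cell-cycle inhibitor p27. miR-146a, a regulator of inflammatory signalling, reached a 2.14-fold difference, and miR-224 reached a log2 ratio of 0.83 ± 0.15. miR-34a, a p53-induced miRNA, reached 0.69 ± 0.06. On the opposite side were miR-106a, at -1.04 ± 0.10, and miR-20a, at -0.90 ± 0.14, both members of the growth-promoting miR-17 family. At 48 h 2 miRNAs passed, miR-592 at 0.70 on the side of miR-22 and miR-203, a miRNA of differentiating epithelium, at -0.70. At 24 h none did. With the rule set on the mean of both arrays, an alternative added after seeing the data, 9 passed at 24 h, all of them opposite to miR-22 and carried by replicate 1, where they lay at -1.22 or below against -0.35 to 0.14 on replicate 2. By that rule 8 passed at 48 h (3 on its side, 5 opposite) and 26 at 96 h (15 on its side, 11 opposite). The 24 h values of miR-221, miR-222 and miR-106a are missing because outlier spots were left out.

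**Figure D2:**
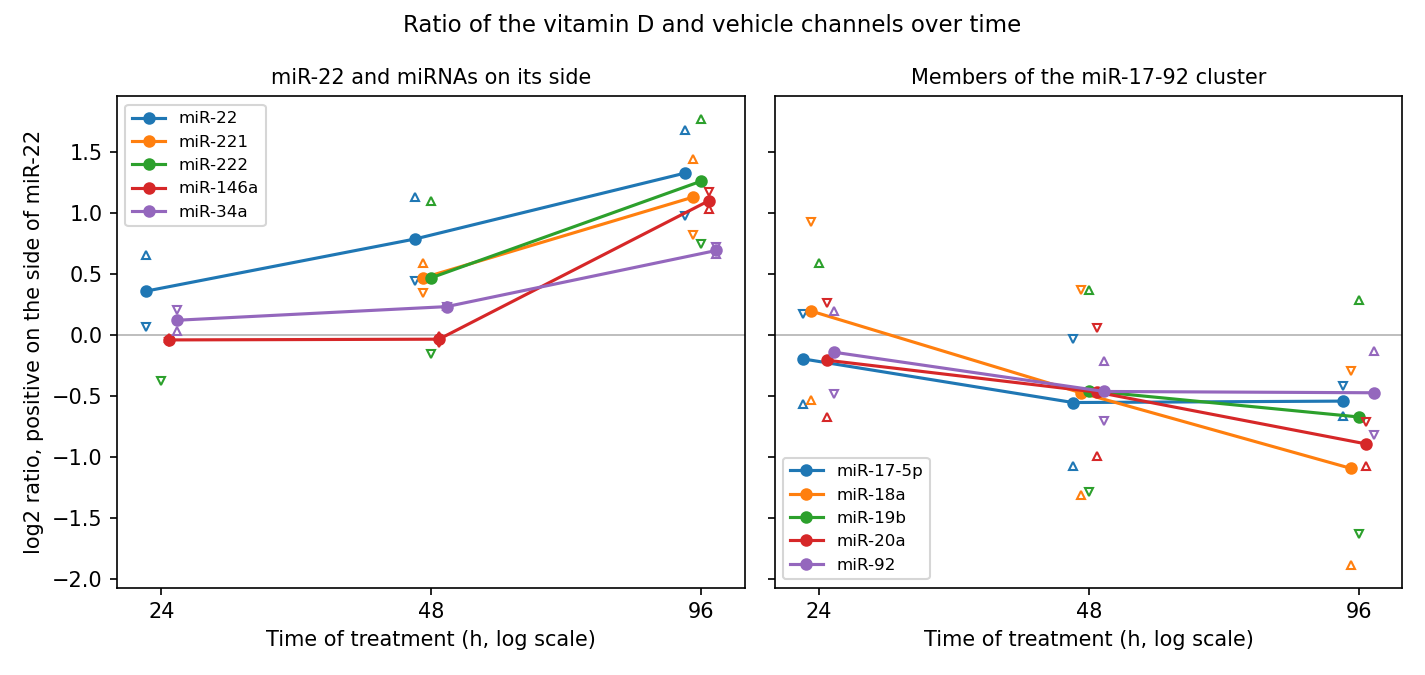
The y axis gives the log2 ratio of the vitamin D and vehicle channels, positive on the side of miR-22, against treatment time in hours on a log scale. Filled points joined by lines are means of the 2 arrays, and open triangles are single arrays (pointing up for replicate 1, down for replicate 2); miR-22 rose from 0.36 to 1.32 on this scale while miR-18a went from 0.19 to -1.09.

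The mean effect over the 3 times passed an adjusted p of 0.05 for 0 of 440 miRNAs in limma, with 17 on the side of miR-22 and 15 on the opposite side at an unadjusted p under 0.05; the smallest adjusted p was 0.558. Of the 399 miRNAs measured on all arrays, 12 lay on one side on all 6 arrays. Single arrays keep the dye effect, with opposite signs on the 2 replicates, so a miRNA whose dye effect exceeds its difference cannot pass. miR-20b did not, with a dye effect of -0.94, though its means were -0.25, -0.63 and -1.20 at the 3 times. The count therefore does not show how many differences repeat in side. Independent arrays would give 3.12% by chance, but arrays of the same replicate number share a dye effect, so this count was not tested. On the side of miR-22 these included miR-532, with a mean of 0.38 ± 0.25 (SD, n = 3 times), miR-551a with 0.37, miR-34a with 0.35, miR-362 with 0.34, miR-28 with 0.24, miR-345 with 0.16 and miR-324-3p with 0.14. The opposite side held miR-503, with -0.37 ± 0.21 (SD, n = 3 times). miR-509, miR-520a* and miR-524 had means of 0.02, 0.03 and -0.03 on dim spots. Over miRNAs above the blank spots, the time-point values correlated at 0.15 between 24 and 48 h, 0.17 between 24 and 96 h and 0.46 between 48 and 96 h.

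Effects that grew with time were sought as a slope on log2 time. On the dye-swap averages, 0 of 399 miRNAs passed an adjusted p of 0.05 in limma, with 27 at an unadjusted p under 0.05. With the 6 arrays fitted separately and the replicate block, 3 of 457 passed. miR-18a, which belongs to the miR-17-92 cluster, had a slope of -0.64 ± 0.04 per doubling of time (adjusted p = 0.00891), and miR-22 had 0.48 ± 0.04 (adjusted p = 0.0132). miR-18b, chosen after its values were seen, went from 0.29 at 24 h to -0.99 at 96 h (adjusted p = 0.0250). With outlier spots kept, 10 of 469 passed in that fit, 4 on the side of miR-22 and 6 on the other. These were miR-22, miR-221, miR-222 and miR-660 on one side, and miR-17-3p, miR-18a, miR-18b, miR-20a, miR-20b and miR-106a on the other; miR-660 and miR-17-3p were chosen after their values were seen. These p-values cover the spread between arrays of the same extracts.

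Among the lists, the miR-17-92 cluster and its paralogs, which promote proliferation and are often raised in colon tumours, lay on the opposite side from miR-22. Of 12 tested members 11 were on that side, and 7 had an unadjusted p under 0.05; 0 passed over all miRNAs and 5 passed adjusted over the list alone. Member means were -0.86 for miR-106a, -0.69 for miR-20b, -0.57 for miR-19b and -0.52 for miR-20a, where miR-106a and miR-19b lack a 24 h value. With outlier spots kept, which gives each of them all 3 times, the means were -0.61, -0.65, -0.43 and -0.56 in the same order. Other members lay near 0 or on the side of miR-22 at 96 h, with miR-106b at -0.05, miR-363 at -0.05 on dim spots and miR-25 at 0.16; these 3 were chosen after their values were seen. The list mean was -0.07 at 24 h, -0.36 at 48 h and -0.58 at 96 h over the 10 members measured at all times, and its 96 h median of -0.63 lay at percentile 0.01 of 10000 random lists matched on intensity. The camera test gave an adjusted p = 0.000306 with the preset correlation, and an adjusted p = 0.768 with an estimated correlation. The directional fry test gave an adjusted p = 0.471 and passed for none of the 15 tested lists. The mixed fry test, which asks whether members change in either direction, passed for the miR-23/24/27 clusters and the vitamin D responsive list, each with an adjusted p = 0.00610. Over 24 alternatives the adjusted p of the miR-17-92 list in camera ranged from 5.585e-09 to 0.768, and the mean of that list lay on the same side in each of them. All but the estimated correlation kept the preset correlation, so the low values rest on that assumption.

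The miR-23/24/27 clusters had a mean of -0.16 over the 3 members measured at all times, with an adjusted p = 0.0354 in camera and 0.768 with an estimated correlation. Over the alternatives its adjusted p ranged from 0.00495 to 0.768. Of 5 tested members 3 lay opposite to miR-22, and 2 passed adjusted over the list alone, miR-27b at -0.30 and miR-27a at -0.19. This call was lost with outlier spots kept, where all 5 members had values at all times, the mean was -0.05 and the adjusted p was 0.638, and in the 6-array fit with the replicate block, where the adjusted p was 0.0533.

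The other 13 tested lists did not pass in camera. Under at least 1 alternative 6 of them did: the intestinal epithelial, miR-125/99/100, miR-15/16, miR-30, miR-34, and neural and liver lists. The miR-125/99/100 family had a mean of 0.15 (adjusted p = 0.0643, from 0.000975 to 0.844 over alternatives), in which miR-125a reached 0.95 and miR-99b 0.70 at 96 h. The miRNAs raised in mesenchymal cells had a mean of 0.11 and a median of 0.01 (adjusted p = 0.601 in camera) over the 8 members measured at all times. Among them were miR-22 and miR-21, the latter at 0.59 at 96 h. These 8 leave out miR-221 and miR-222. Over all 10 members, with outlier spots kept, the mean was 0.21. The list of vitamin D responsive miRNAs in other cells had the same mean, 0.11, a median of 0.02 and the same adjusted p. Of its 12 tested members 1 passed adjusted over the list alone, miR-27b at -0.30, opposite to miR-22. Its members miR-22 and miR-146a did not. The mesenchymal and vitamin D lists both hold miR-22, whose side is positive by convention and whose mean was 0.82. A positive mean of these lists is thus in part given by the convention. Oncomirs raised in colorectal cancer were split, with 5 on the side of miR-22 and 7 on the other (mean -0.10, adjusted p = 0.398). The intestinal epithelial list had a mean of -0.04 and a median of 0.04 (adjusted p = 0.601), so its mean and median differ in sign. The miR-15/16 family had a mean of -0.12 (adjusted p = 0.460), the miR-34 family 0.14 (adjusted p = 0.601) and the miR-30 family 0.03 (adjusted p = 0.601). Lists of markers of other cell types had means of 0.01 for haematopoietic, 0.04 for endothelial and muscle, and -0.05 for neural and liver miRNAs, over members that went both ways. The chromosome 19 cluster had a mean of -0.02 and the embryonic stem cell cluster -0.01, each with an adjusted p = 0.601, as had the 3 marker lists.

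Lists with fewer than 3 members measured at all times were not tested. The means at 96 h with outlier spots kept were 1.09 for the pair of miR-221 and miR-222, 0.14 for the let-7 family, 0.13 for the miR-200 family, 0.10 for the miR-181 family, 0.01 for miR-143 and miR-145 and -0.42 for the miR-29 family. With outlier spots left out, both tested members of the miR-29 family passed adjusted over the list alone, miR-29a at -0.24 and miR-29c at -0.18. With them kept these means were -0.14 and -0.15, and miR-29a lay at 0.07 at 48 h.

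**Figure D3:**
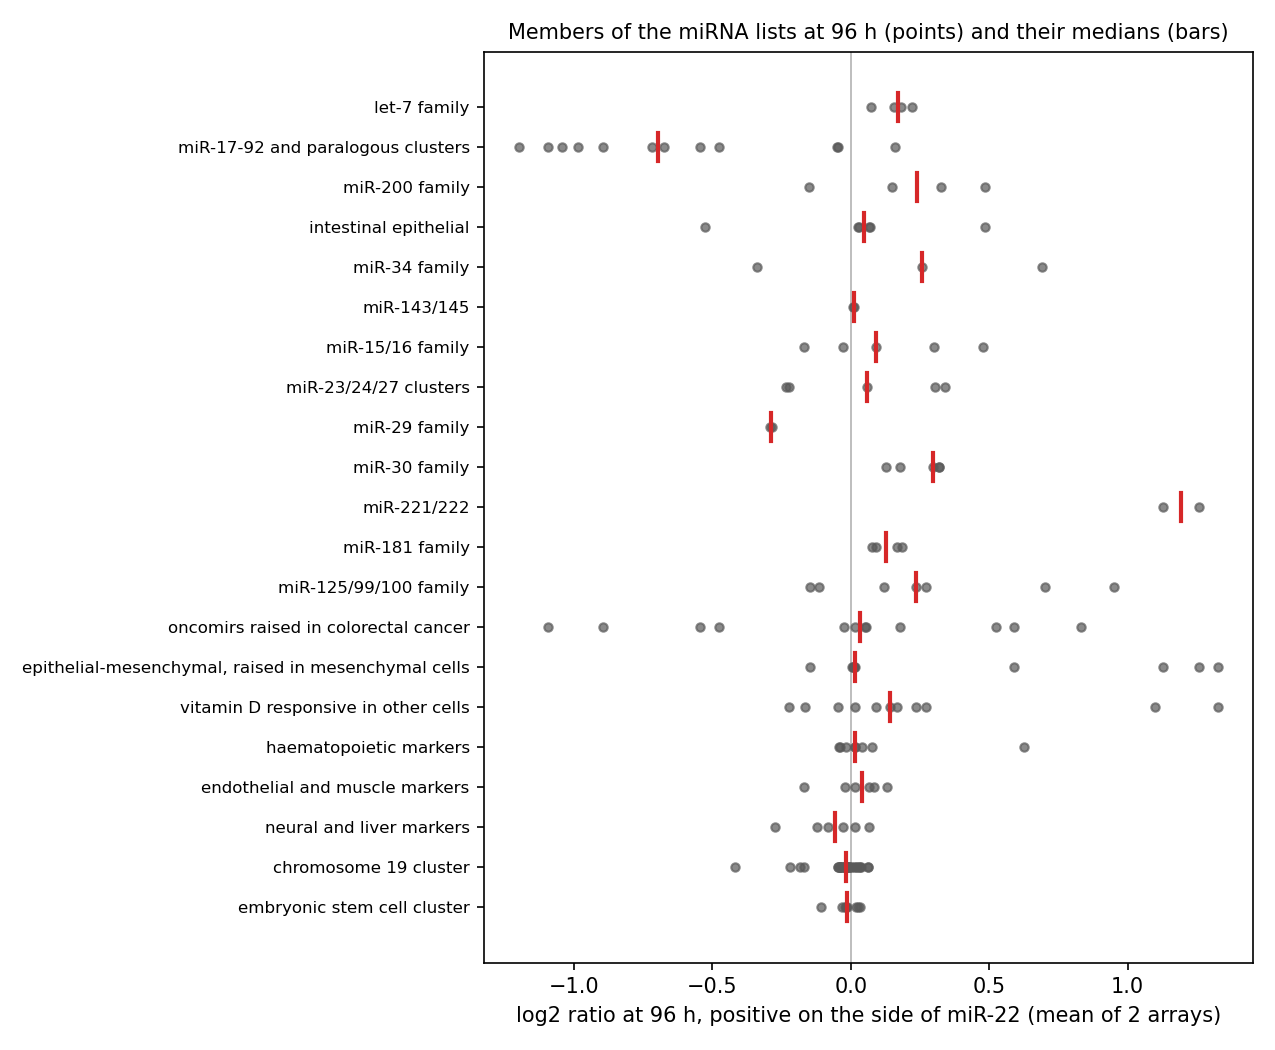
Each point is 1 miRNA of the list named on the y axis, and the x axis gives its log2 ratio at 96 h as the mean of 2 arrays, positive on the side of miR-22; bars mark list medians. Most members of the miR-17-92 list lay below 0 and both miR-221 and miR-222 lay above 1.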

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

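The 96 h minus 24 h difference of the effect passed an adjusted p of 0.05 for 3 miRNAs in the 6-array limma fit with the replicate block, a contrast chosen after the data had been seen. The difference was -1.29 for miR-18a, 1.14 for miR-146a and 0.97 for miR-22, on the scale where miR-22 is positive. With outlier spots kept, 15 passed. The tests of the dye swap, of cross-hybridisation and of values with the dye and intensity trends removed, below, were also chosen after the values were seen.

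The first pattern is that the 2 arrays of a time moved in opposite directions between 24 and 96 h. An absence of any dye swap, as the dye fields read, needs a positive correlation, and it was -0.40 over 354 miRNAs (Spearman -0.25), between -0.21 and -0.56 under other processing. Under that reading 99 miRNAs would pass in the mean test, which would then hold the dye effect, whose SD over miRNAs was 0.31. Which array of each pair has the right fields stays open.

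The second pattern is the wider differences at 96 h. Over miRNAs above the blank spots the SD was 0.23 at 24 h, 0.19 at 48 h and 0.28 at 96 h, so it did not grow steadily. For miRNAs not above them it was 0.14 at 24 h, 0.07 at 48 h and 0.03 at 96 h, so noise of dim probes was largest at 24 h. The order of the SDs thus does not decide whether the differences grew steadily. Noise of single spots is argued against by probes named for rat, mouse or zebrafish miRNAs: their 96 h values correlated with those of the human probe of the same name at 0.83 (n = 103). Some probes differed: the zebrafish miR-146a probe gave 0.12, the zebrafish miR-18b probe -0.24 and the mouse miR-17-3p probe -0.25, all smaller than the human values, so for these miRNAs the other probes do not speak against noise. Leftover dye bias could contribute, since the 96 h values correlated with the dye effect at 0.296 (n = 376). This lay under the limit of 0.3 written beforehand, but within 1 SE of it (upper bound 0.343), so a contribution stays open. Exchanged dyes cancel a dye effect only where it is equal on both arrays. The correlation with mean intensity, rho = 0.21, lay under the same limit by more than 1 SE (upper bound 0.260), which argues against a curve left by loess as the main source. The use of 1 SE was settled after the values had been seen; with 95% bounds the intensity explanation would stay open too. A trend on the dye effect took up 8.76% of the variance and a curve on intensity 3.56%. With both removed the 7 miRNAs of the size rule that have a dye estimate still differed by at least 1.5-fold in the mean of both arrays. With intensity alone removed 6 did, miR-34a falling to 0.58. These miRNAs had been picked from the same values by a stricter rule, and the trends hold little of the variance. A trend over all miRNAs also cannot remove a dye bias of a single probe, so this check does not decide the dye explanation. miR-221 has no dye estimate. The 96 h arrays lie on 1 slide that holds no other time, so the slide and the time cannot be told apart. A biological growth of the effect with time stays among the open explanations.

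The third pattern is the miR-17-92 group opposite to miR-22 at 96 h. Cross-hybridisation among the similar miR-17, miR-18, miR-20, miR-93 and miR-106 probes alone would leave miR-19a, miR-19b and miR-92 near 0. Yet their mean was -0.62 ± 0.07 (SE, n = 3 miRNAs), with values of -0.72, -0.67 and -0.48. All 3 were measured on the same 2 arrays, so this SE does not cover the spread between extracts. miR-19a and miR-19b share a family number, and cross-hybridisation between their probes was not tested, so the 3 may not be separate readings. A common change of the cluster transcript is a candidate explanation that these arrays, with 1 pair of extracts per time and an unsettled direction, leave as a hypothesis. miR-363 shares the cluster of miR-106a, miR-20b and miR-18b and lay at -0.05 against -1.04, -1.20 and -0.99, but its mean log2 intensity of 6.09 is among the limits set by the blank spots, 5.89 to 6.44, so its value decides nothing.

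Probes outside the human set also gave signal above the blank spots. These were 368 of 431 named for rat, mouse or zebrafish miRNAs and 253 of 344 of other names, mostly predicted, worm and fly miRNAs. Of the human names 415 of 469 did so. A signal above the blank spots thus does not by itself show that a miRNA was present.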

How the results depend on the processing

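Alternatives on outlier spots, blank spots and the 1.5-fold mean rule were added after the data had been seen. The count of 0 in the mean test held in every setting except the dye fields read literally, which gave 99. The trend count of 0 became 3 with the replicate block and 10 with that block and outlier spots kept; in the fit with the replicate block the miR-23/24/27 list had an adjusted p = 0.0533, in a range over alternatives from 0.00495 to 0.768. The size rule at 24 h gave 0 as planned, 12 with literal fields, 1 with an offset of 16, 3 with no background correction, 4 with the scanner's log ratios, 4 with the deposited table, 2 at 1.3-fold, 7 at 2-fold of the mean and 9 at 1.5-fold of the mean. At 48 h the 2 became 12 with literal fields, 0 with no background correction, 4 at 1.3-fold, 0 at 2-fold of the mean and 8 at 1.5-fold of the mean. At 96 h the 8 became 20 at 1.3-fold and 26 at 1.5-fold of the mean. The 2 list calls became 4 with literal fields, 0 with an estimated correlation, and 1 with an offset of 16, the scanner's log ratios, median centring, the deposited table, the arrays fitted without or with the block, outlier spots kept (with or without the block), or the 24 h or 48 h pair left out; without single arrays they ranged from 1 to 5. The call kept in most of these was the miR-17-92 list, lost with literal fields and with an estimated correlation. All settings but the last used the preset correlation of 0.01, so they do not test that assumption. The correlation estimated for this list was 0.36, and the adjusted p in camera was then 0.768.

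The correlation between orientations of the change from 24 to 96 h (-0.40) was -0.26 with no background correction, -0.22 with the scanner's log ratios, -0.21 with the deposited table, -0.56 with scaling between arrays and -0.49 with outlier spots kept. From 48 to 96 h (-0.49) it was -0.39, -0.23, -0.23 and, with median centring, -0.60; from 24 to 48 h median centring gave -0.38. The cause was not tested, except that with exchanged dyes the literal reading leaves the dye effect in place of the treatment difference.

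With literal fields, values that turned in sign and pass the threshold under that reading, though not in the main analysis, were list means of 0.31 (intestinal epithelial) and 0.19 (neural and liver), and values of 0.89 for miR-19b, -1.59 for miR-141, -0.74 for miR-200a, 0.37 for miR-424, -0.47 for miR-195, 0.44 for miR-29c, 0.98 for miR-30b, -0.28 for miR-181c, -0.43 for miR-181d, 0.69 for miR-10a, 0.49 for miR-10b, 0.31 for miR-92, 0.19 for miR-9 and 0.27 for miR-219; values called by the size rule turned too, with miR-592 at -0.013 and miR-203 at 0.032 at 48 h, and miR-146a at -0.069 and miR-224 at -0.067 at 96 h. The 96 h value of miR-34a turned too with literal fields, its arrays lying at 0.67 and 0.72 in the main direction. Without single arrays the miR-30 list ranged from -0.23 (without 96 h replicate 1, past the threshold) to 0.295 (without 24 h replicate 2). A first reading counted every change of sign as a reversal. After its outcome was seen, values that pass no threshold were set against their SD over times instead. Among named miRNAs and lists, uncalled ones included, the sign changed in 37 values with literal fields, in 57 of 1446 values under 15 other settings, in 20 of 259 without a time and in 110 of 582 without an array, where the lone array keeps its dye effect. miR-22 lay between 0.57 (without the 96 h pair) and 1.05 (without the 24 h pair) in the other settings; the 0.33 with literal fields is its dye effect. Size-rule counts were not run without single arrays, since the rule needs both. Signal over background limits the dim probes: 238 of 469 miRNAs lay above the blank spots on all 6 arrays.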

Other observations

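The first test of neighbouring genes below was set out before its result was seen. Those among miRNAs of similar intensity and without the miR-17-92 families were added afterwards. The one among pairs above the blank spots was also added afterwards, but was set out before its own result was seen. Of the miRNAs whose values follow, miR-146b, miR-7, miR-138 and miR-23a were chosen after their values were seen. miR-532 and miR-362, whose genes neighbour each other, reached 0.66 and 0.59 on the side of miR-22. miR-146b, whose gene lies on another chromosome from that of miR-146a, reached 0.78 ± 0.07 after -0.08 at 48 h. Cross-hybridisation between the miR-146a and miR-146b probes was not tested, so these may not be 2 separate changes. miR-7, a repressor of growth factor signalling, lay at -0.70 ± 0.10, and its rat probe gave -0.70. miR-138 lay at 0.92 ± 0.12 at 96 h, but its arrays differed in side, with -0.19 on replicate 1 and 2.03 on replicate 2, and its dye effect of -0.93 was about as large as that mean.

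One hypothesis was that miRNAs whose genes lie within 10 kb of each other change together, as members of one transcript would. Names were matched for 316 of 376 miRNAs in RefSeq's annotation of GRCh38.p14, used here only for which genes are neighbours. Families were told apart only by the number in the miRNA name, with the miR-17 family taken as 1. Members of a single listed family thus stayed in as pairs, such as miR-195 with miR-497 and miR-424 with miR-503. Pairs within the chromosome 19 cluster stayed too, and the likeness of their sequences was not tested. Cross-hybridisation between similar probes was therefore not removed from these tests. In 255 pairs of neighbours from families told apart in this way, the mean absolute difference at 96 h was 0.12. The average was 0.28 in 10000 permutations of the values over the 124 miRNAs (permutation p = 1e-04, the smallest they can give). Neighbours also share intensity, and dim probes lie near 0. When values were permuted only among miRNAs of similar intensity, the average was 0.19 and the permutation p was again 1e-04. Most of these pairs hold dim probes. In the 47 pairs with both members above the blank spots on all 6 arrays, the difference was 0.24 against 0.52 (permutation p = 1e-04, again among miRNAs of similar intensity), and in the 35 of them outside the miR-17-92 families 0.23 against 0.32 (permutation p = 0.0058). Some neighbours went apart: miR-23a lay at 0.30 and miR-27a at -0.23, and miR-23b at 0.34 and miR-27b at -0.22. Pairs share members, so they are not independent. That neighbours change together thus stays a hypothesis from 1 pair of extracts, and a shared transcript as its source was not tested.

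The real signs of the 3 time-point values gave 32 miRNAs at an unadjusted p under 0.05 in the mean test, and the highest of the other 3 sign patterns gave 17. Only 1 of the 4 patterns, the real one, gave as many, but 4 patterns are too few for a share under 0.05.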
